A study of Mus musculus with 610 samples.

How the data were processed

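Single cells of 4 sorted thymus populations were captured on a Fluidigm C1, lysed and reverse transcribed. Per the labels' protocols, the complementary DNA then went through 18 cycles of preamplification with pooled primers, and each of the 48 assays was read by quantitative PCR of 30 cycles with EvaGreen dye and a melt curve. The deposited table holds 1 threshold cycle (Ct) per assay and cell, not normalised, for 29280 reactions. A low Ct is a high expression: this was read from the values, in which Gapdh has the lowest mean. Values ran from 6.01 to 24, and 50.5% of reactions stood at exactly 24, which was taken as not detected. How Ct was called, how melt curves were used, who set the ceiling and which capture sites were dropped is not given in the sources used here. No 2 cells held identical values, and each of the 610 columns matched 1 sample by its title.

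Level was computed as 24 minus Ct, so that an undetected reaction is 0, and 1 unit is 1 PCR cycle. Differences of level are given in cycles, not as folds. A gene was called detected in a cell when its level was above 0. Cells were not treated as replicates. The run, read from the token in each cell's title, was the replicate, and each gene had 1 value per run: the mean level over all cells, or the empirical logit of the share of cells with the gene detected (0.5 added to each side), or the natural log odds ratio of being detected with Sox13 (0.5 added to each cell of the 2 by 2 table). No label names the animals behind a run. P-values measure the spread between runs, which may be technical in part. There were 3 runs of B6 DN1d, 3 of Rag1-/- cKit-, 1 of Tcrd-/- DN1d and 1 of B6 DN2. No batch holds more than 1 group, so run and group cannot be told apart.

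Each measure was fitted with limma 3.58.1 in R 4.3.3, all 8 runs in 1 fit with a mean per group, which leaves 4 residual degrees of freedom. The groups with 1 run were assumed to vary like those with 3. A gene detected in no cell of a group adds no spread of level there, so that its SE can be too small. P-values were adjusted by Benjamini-Hochberg over the 47 assays detected in any cell, or over the 41 other genes detected in 5% to 95% of all cells for co-detection, with a threshold of 0.05. limma's moderation gave 4.97 total degrees of freedom for level, 20.0 for detection and 164 for co-detection, where the spread was in effect pooled over genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of single shares are exact (Clopper-Pearson) at 95%. A count of 0 allows up to 3 cells of the total. Both cover counting error only.

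Comparisons, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named all genes past the threshold where these were 25 or fewer, otherwise the 25 with the largest difference, and in each comparison Sox13, Sox4, Maf, Blk, Tcf7, Bcl11b, Gata3, Id3, Zbtb16, Rag1 and any Tcrd assay. For co-detection it named the 15 largest log odds ratios past the threshold and Maf, Blk, Sox4 and Bcl11b. A further gene that the rule named is not reported here, though the counts include it. The lists with 2 or more members in the panel were the Tgd17 programme (11), T lineage specification (10), multipotent progenitor (2), innate lymphoid (4), T cell receptor loci (3) and HMG box and Wnt pathway (5). The type 1 effector list had only Tbx21, the TCR signal response list Egr2 and the reference list Gapdh, none of them past the threshold for level or detection in any comparison. The level of Tbx21 varied widely between the B6 DN1d runs, 5.10 ± 2.94 (SD, n = 3), which weakens its tests of level. The cell cycle list had Cdk6, and the myeloid and dendritic list Csf1r. The B cell and cell presence lists had 0 members. Of the 48 assay names, 43 matched a RefSeq symbol of assembly GRCm38.p6 and 2 a synonym, and the 3 junction assays matched none.

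The tests were run on simulated data before use, with 20 panels of cells whose shares and levels were set from B6 DN1d. For level and detection each gene was drawn independently, so that links between genes within a cell and shifts of a whole run were absent. The co-detection panels held the planted links only and no spread between runs beyond the sampling of cells. The rates of calls below hold for these settings and may differ in the real data. Of unchanged genes, 0.9% were called for level in each comparison, and 1%, 1.1% and 1.4% for detection in DN2, Tcrd-/- and Rag1-/- cells against B6 DN1d. For detection, a planted logit shift of 2 was called for 33.8% of genes in DN2 against DN1d, 47.5% in Tcrd-/- against B6 DN1d and 86.2% in Rag1-/- against B6 DN1d, over 47 genes. For co-detection in B6 DN1d, over 39 genes, 85% of planted log odds ratios of 1.5 and 1% of unassociated genes were called. Because these simulations did not cover rare genes, Sox13 was also shuffled among the cells of each run 100 times and the co-detection fits were repeated, a check chosen after the data were seen. The test of an equal gain in the Tcrd-/- run lowered each of its levels by 2 cycles, set levels below 0 to 0 and repeated the detection fit. The log odds ratios between 5 genes in Sox13-undetected cells were set against 1000 shuffles and 1000 random sets of 5 other genes, chosen after the data were seen. The alternatives were stricter detection limits, leaving out the 21 cells with few detected genes (more than 3 median absolute deviations below the median of their run), other summaries of level and detection, adjustment for the number of other genes detected, Gapdh normalisation, other fits, other measures of co-detection, and leaving out each run. A limit of detection of 20, pseudocounts in proportion to the margins and a minimum of 5 cells on each side were added after the data were seen.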

Results

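The study measured the expression of 48 assays in 610 single cells sorted from the mouse thymus, to describe progenitors of the gamma delta T cells that make interleukin 17 (Tgd17 cells). There were 4 sorted populations. B6 DN1d cells came from C57BL/6J mice of postnatal days 7 to 10 and were negative for the T cell receptor delta chain, lineage markers, CD25 and cKit and positive for CD44 and CD24. They gave 223 cells in 3 runs of 72, 70 and 81 cells. Tcrd-/- DN1d cells, from mice with a targeted T cell receptor delta gene (allele Tcrd tm1Mom), passed the same gate at the same ages and gave 86 cells in 1 run. Rag1-/- cKit- cells, from mice that lack the recombinase gene Rag1, were CD44 positive, CD25 negative and cKit negative, were taken on postnatal days 0 to 2 without a CD24 gate, and gave 223 cells in 3 runs of 89, 52 and 82 cells. B6 DN2 cells were sorted as positive for CD44, CD25 and cKit, and so differ from DN1d cells in both CD25 and cKit. They came from C57BL/6J mice of postnatal days 7 to 10 and gave 78 cells in 1 run. Level below means 24 minus the threshold cycle, a log2 scale on which an undetected reaction is 0, averaged over the cells of a run. Means carry the SD between runs. For the groups with 1 run the share of cells carries an exact (Clopper-Pearson) 95% interval, which covers counting error only.

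A mean of 19.8 ± 0.528 of the assays (SD, n = 3 runs) was detected per B6 DN1d cell and 23.1 ± 1.40 (n = 3) per Rag1-/- cell. The mean was 30.9 in the Tcrd-/- run and 28.5 in the DN2 run. The housekeeping gene Gapdh was detected in all 610 cells, and its mean level per run lay between 14.2 and 15.6. Its level was 14.64 ± 0.46 (n = 3) in B6 DN1d, 15.18 ± 0.42 (n = 3) in Rag1-/-, 15.14 in the Tcrd-/- run and 15.16 in the DN2 run. The junction assays read rearranged T cell receptor genes, which Rag1-/- cells cannot make. Vg2-Jg1 and Vd4-Jd1 were each detected in 0 of 223 Rag1-/- cells, which allows a share of up to 1.35%. In B6 DN1d cells they were detected in 41% ± 9.53 and 7.29% ± 2.55 of cells (n = 3). Rag1 itself and Id3 were not analysed here. Vd5-Jd1 was detected in 0 of the 610 cells and was not tested.

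**Figure D1:**
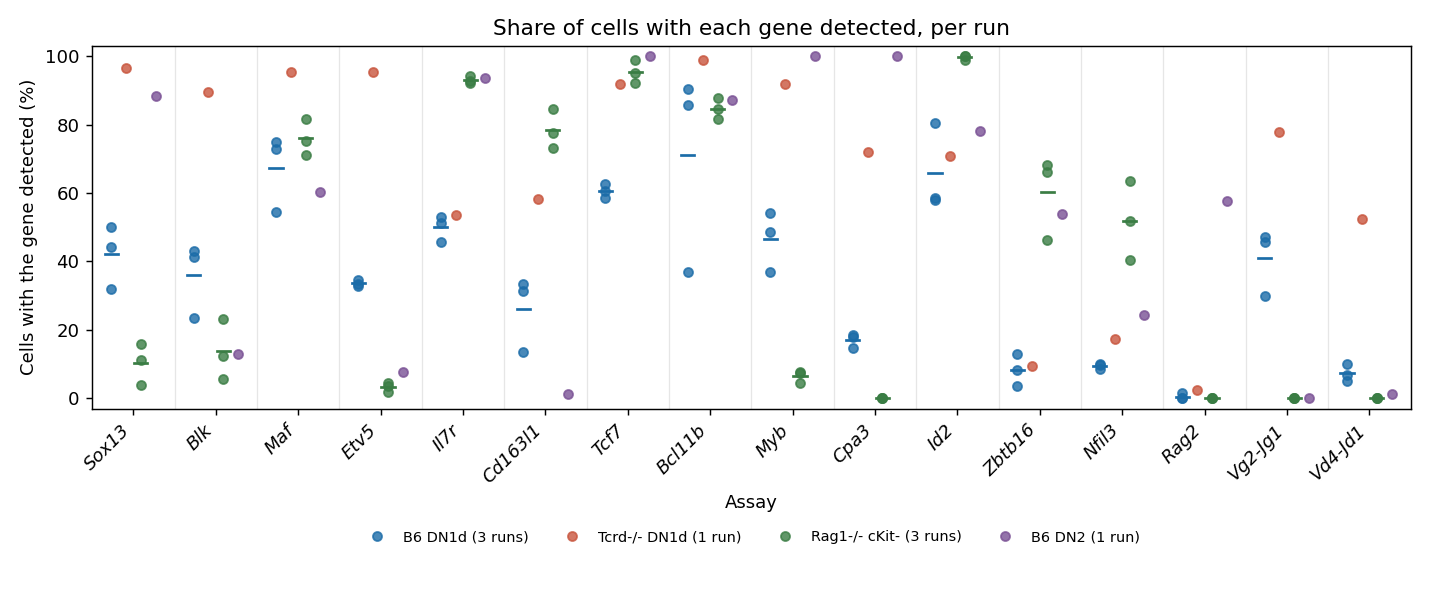
Share of cells (percent, vertical axis) in which each of 16 assays (horizontal axis) was detected, with 1 point per run and a short line at the mean of the groups with 3 runs. Sox13 was detected in 96.5% of Tcrd-/- DN1d cells and in 32.1% to 50% of the cells of the B6 DN1d runs, and Id2 in at least 98.9% of the cells of each Rag1-/- run.

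The first comparison asked how DN1d cells differ from the DN2 stage. Genes such as Cpa3, Notch1 and Myb were detected in far more DN2 cells, and several genes of the Tgd17 programme were detected in few of them. Cpa3, which encodes a mast cell and progenitor protease, was detected in 100% of DN2 cells (95.4% to 100%) and in 17.1% ± 2.04 of B6 DN1d cells (n = 3). Its level was 9.90 ± 0.15 cycles (SE) higher. This SE is likely too small, since it draws on Rag1-/- runs with Cpa3 in 0 cells and holds no spread between DN2 runs. Notch1, the receptor that drives T lineage commitment, Myb, Syk, Cdk6, Runx1, Tcf7 and the E47 form of Tcf3 were also detected in 100% of DN2 cells. Their shares in B6 DN1d cells were 33.9%, 46.6%, 27.3%, 37.5%, 66%, 60.5% and 31.3%. By detection, 21 of the 47 tested genes were detected in more DN2 cells and 10 in fewer (limma on 1 value per run, Benjamini-Hochberg). By level, 19 were higher and 8 lower.

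Of the 11 Tgd17 programme genes, 4 were detected in more DN2 cells, 3 in fewer and 4 did not pass the threshold. Adjusted over the list alone, 4 were detected in more cells and 4 in fewer. Sox13, an HMG box factor of this lineage, was among the genes detected more often, in 88.5% of DN2 cells (79.2% to 94.6%) against 42.1% ± 9.14 (limma, adjusted p = 0.000758). Where Sox13 was detected, its mean level was 7.16 in DN2 cells and 9.44, 8.92 and 10.2 in B6 DN1d runs 1 to 3. The check of level in detected cells did not cover Sox13, which was detected in only 2 cells of Rag1-/- run 2. Il7r, Sox4 and Tcf12 were detected in 93.6%, 100% and 96.2% of DN2 cells. Cd163l1 and Etv5 were detected in 1.28% and 7.69% of DN2 cells against 26.1% ± 10.9 and 33.6% ± 0.969. Blk, a Src family kinase, was detected in 12.8% against 36% ± 10.9 and did not pass (adjusted p = 0.0507), and Maf was detected in 60.3% against 67.4% ± 11.4 (adjusted p = 0.560). By level the list gave 4 higher, 3 lower and 4 not past the threshold, with 4 higher and 4 lower adjusted over the list alone. Of the 10 T lineage specification genes, 6 were detected in more DN2 cells, 1 in fewer and 3 did not pass, with the same counts of 6 and 1 adjusted over the list alone. Rag2 was detected in 57.7% of DN2 cells (46% to 68.8%) and in 0.476% ± 0.825 of B6 DN1d cells, and Lef1 in 7.69% against 48.3% ± 1.98. Bcl11b, detected in 87.2% against 71% ± 29.5, and Gata3, detected in 100% against 98.6% ± 1.43, did not pass. By level 5 of the list were higher, 1 was lower and 4 did not pass, with 5 and 1 adjusted over the list alone.

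Both multipotent progenitor genes, Spi1 and Myb, were higher in DN2 cells by detection and by level, also adjusted over the list alone. Spi1, which encodes PU.1, was detected in 80.8% of DN2 cells against 6.95% ± 4.90. Of the 4 innate lymphoid genes, Zbtb16 and Tox were detected in more DN2 cells, Zbtb16 in 53.8% (42.2% to 65.2%) against 8.30% ± 4.58, and Id2 and Nfil3 did not pass. The count of 2 was the same adjusted over the list alone for detection, while for level it was 2 of 4 over all genes and 0 of 4 over the list alone. Of the 5 HMG box and Wnt pathway genes, 4 were detected in more DN2 cells and 1, Lef1, in fewer, by detection and by level and also adjusted over the list alone. Both tested junctions were detected in fewer DN2 cells, Vg2-Jg1 in 0 of 78. By level only Vd4-Jd1 passed, and adjusted over the list alone neither did. Csf1r, a myeloid and dendritic gene, was past the threshold by detection (adjusted p = 0.00558) with 2 of 78 DN2 cells and 0 of 223 B6 DN1d cells, too few to carry weight. Other genes detected in more DN2 cells were Smo, Dna2 and Mcm2, the last in 97.4% against 30.3% ± 4.10, and other genes detected in fewer were Ccr9, Csf2rb2, Gp49a and Gpr183. DN2 cells came from 1 run, assumed to vary like the groups with 3 runs, and run and population cannot be told apart. The level count was the less stable, falling from 27 to 17 without Rag1-/- run 1 or run 3, to 14 with the median over cells, and to 3 of 30 genes in cells with the gene detected. The lower calls nearly vanished, with 8 falling to 1 without Rag1-/- run 1, to 2 without Rag1-/- run 3 or B6 DN1d run 1, and to 0 with the median and in cells with the gene detected. The level calls of Gp49a, Gpr183, Lef1, Scart2, Sox13, Sox4, Tox, Vd4-Jd1 and Zbtb16 and the detection call of Vd4-Jd1 ended when single runs were left out, and Tox differed by -0.0169 cycles in cells with the gene detected. The higher share of Sox13 turned to a difference of -0.363 on the logit scale (adjusted p = 0.574) when adjusted for the number of other genes detected in the cell.

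The second comparison asked how DN1d cells differ in Tcrd-/- mice. Most genes of the Tgd17 programme were detected in more Tcrd-/- than B6 DN1d cells. Sox13 was detected in 96.5% of Tcrd-/- cells (90.1% to 99.3%) against 42.1% ± 9.14 (n = 3), a level difference of 7.30 ± 0.62 cycles (SE; limma, adjusted p = 0.000636). Etv5, an ETS factor, was detected in 95.3% against 33.6% ± 0.969, Blk in 89.5% against 36% ± 10.9 and Maf in 95.3% against 67.4% ± 11.4. The Vd4-Jd1 junction was detected in 52.3% of Tcrd-/- cells (41.3% to 63.2%) against 7.29% ± 2.55, so that these delta segments were present and rearranged in the mutant mice, and Vg2-Jg1 in 77.9% (67.7% to 86.1%) against 41% ± 9.53. By level, 29 of 47 genes were higher and 0 lower, and in cells with the gene detected only, 2 of 30 genes passed. By detection, 26 were detected in more cells and 0 in fewer (limma, 1 value per run). With cells with few detected genes left out, 26 were detected in more cells and 5 in fewer. The genes in fewer cells were Bhlhe40, Cdh1, Csf2rb2, Gp49a and Spi1. Before the filter their differences were -0.681, -0.491, -0.784, -0.589 and -0.522 on the logit scale. The filter left out 8 Tcrd-/- and 0 B6 DN1d cells, among them all 3 Sox13-undetected Tcrd-/- cells. It took most Tcrd-/- cells with those genes, so that the lower calls appear only under this unequal filter.

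Of the 11 Tgd17 programme genes, 9 were detected in more Tcrd-/- cells, 0 in fewer and 2, Il7r and Scart2, did not pass. By level 10 were higher and 1, Il7r, did not pass, and adjusted over the list alone the counts were also 9 and 10. The detection calls of Cd163l1 and Il17re and the level calls of Cd163l1, Scart2 and Sox4 ended when single runs were left out. Adjusted for the number of other genes detected, the differences in detection of Cd163l1, Il17re and Blk turned negative. Il7r was detected in 53.5% of Tcrd-/- cells and 50.1% ± 3.86 of B6 DN1d cells. Of the 10 T lineage specification genes, 6 were detected in more cells and 4 did not pass, and by level 8 were higher and 2 did not pass, with 6 and 8 adjusted over the list alone. Runx1 was detected in 98.8% against 66% ± 3.25, Lef1 in 91.9% against 48.3% ± 1.98 and Tcf7 in 91.9% against 60.5% ± 1.96. Bcl11b was detected in 98.8% against 71% ± 29.5, where run 3 of B6 DN1d stood at 37% and the others at 90.3% and 85.7%. Gata3 was detected in 100% of Tcrd-/- cells and its level was 2.12 ± 0.48 cycles higher (adjusted p = 0.0157), with no difference past the threshold in detection. All 5 HMG box and Wnt pathway genes were higher by detection and level, also adjusted over the list alone. Of the 4 innate lymphoid genes only Tox passed (91.9% against 58.6% ± 3.96), as it did adjusted over the list alone. Zbtb16 was detected in 9.30% against 8.30% ± 4.58. Of the multipotent progenitor genes Myb passed (91.9% against 46.6% ± 8.73) and Spi1 did not, and both junctions passed, by detection and level and adjusted over the list alone. The detection and level calls of Bcl11b and the level calls of Tox and Vg2-Jg1 ended when single runs were left out. Adjusted for the number of other genes detected, the differences in detection turned to -0.785 for Tox, -1.19 for Tcf7, -0.485 for Myb and -0.997 for Vg2-Jg1.

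Genes not named above were higher too. Cpa3 was detected in 72.1% of Tcrd-/- cells (61.4% to 81.2%) against 17.1% ± 2.04, the granzyme gene Gzma in 75.6% against 16% ± 6.52, Cdk6 in 91.9% against 37.5% ± 2.79, Smo, a Hedgehog pathway receptor, in 83.7% against 29% ± 2.89 and the chemokine receptor gene Ccr9 in 87.2% against 42.1% ± 9.14. The calls of Ccr9, and the detection call of Syk, ended when single runs were left out, and the difference in detection of Ccr9 turned to -0.266 when adjusted for the number of other genes detected. The gate against the delta chain removes cells that carry it from B6 mice, and would remove none from Tcrd-/- mice if the targeted gene gives no chain, which was not measured here. There was 1 Tcrd-/- run, so run and genotype cannot be told apart, and when detection was adjusted for the number of other genes detected in the cell, 9 genes passed the threshold, 7 of them among the 26.

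The third comparison set Rag1-/- cKit- cells against B6 DN1d cells and differs in genotype, age and the CD24 gate at once. Rag1-/- cells held genes of innate lymphoid cells far more often and held Sox13, Etv5 and Myb less often. Id2, a helix-loop-helix inhibitor that innate lymphoid cells need, was detected in 99.6% ± 0.649 of Rag1-/- cells against 65.7% ± 12.9 of B6 DN1d cells (n = 3 each), a level difference of 7.74 ± 0.43 cycles (SE; limma, adjusted p = 0.000234). Zbtb16, which encodes PLZF, was detected in 60.2% ± 12.2 against 8.30% ± 4.58, Nfil3 in 51.8% ± 11.5 against 9.45% ± 0.717, and Il7r in 93% ± 1.09 against 50.1% ± 3.86. Sox13 was detected in 10.3% ± 6.06 against 42.1% ± 9.14 and Etv5 in 3.36% ± 1.31 against 33.6% ± 0.969. By detection, 16 of 47 genes were detected in more Rag1-/- cells and 12 in fewer. By level, 16 were higher and 10 lower.

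Of the 11 Tgd17 programme genes, 3 rose (Cd163l1, Il7r and Tcf12), 3 fell (Sox13, Blk and Etv5) and 5 did not pass, by detection and by level and with the same counts adjusted over the list alone. The calls of Blk ended when single runs were left out. Cd163l1, a scavenger receptor gene, had the largest level difference of the tested genes, 8.57 ± 0.70 cycles, and was detected in 78.4% ± 5.78 against 26.1% ± 10.9. Maf was detected in 76% ± 5.32 against 67.4% ± 11.4 and Sox4 in 85.6% ± 3.48 against 87.8% ± 2.78, neither past the threshold. All 4 innate lymphoid genes were detected in more Rag1-/- cells and 3 were higher by level, with counts of 4 and 3 adjusted over the list alone. Of the 10 T lineage specification genes, 3 were detected in more cells, 1 in fewer and 6 did not pass, with 3 and 0 adjusted over the list alone. By level 3 were higher and 7 did not pass, with 3 adjusted over the list alone. Tcf7 was detected in 95.4% ± 3.30 against 60.5% ± 1.96, while Bcl11b (84.7% ± 2.97 against 71% ± 29.5) and Gata3 (99.6% ± 0.704 against 98.6% ± 1.43) did not pass.

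Both multipotent progenitor genes were detected in fewer Rag1-/- cells, Myb in 6.5% ± 1.75 against 46.6% ± 8.73, and by level Myb was lower and Spi1 did not pass, with the same calls adjusted over the list alone. Of the 5 HMG box and Wnt pathway genes, Tcf7 and Tox were detected in more cells, Sox13 and Lef1 in fewer and Sox4 did not pass. By level Tcf7 was higher, Sox13 was lower and 3 did not pass, and adjusted over the list alone the counts were the same. Both junctions were lower, also adjusted over the list alone. Rag1-/- cells cannot rearrange these genes, so that the genotype fixed this outcome, and both junctions are in the counts of lower genes by detection and level. The level call of Vg2-Jg1 ended when single runs were left out, as did the detection call of Cdh1 and the level calls of Csf2rb2, E2f2, Gp49a and Syk. Other genes detected in more Rag1-/- cells were Bhlhe40 (59.7% ± 10.0 against 19.4% ± 5.64), Gpr183, Gzma, Cdk6, Mcm2 and Cdh1. Cpa3 was detected in 0 of 223 Rag1-/- cells, and Csf2rb2, Gp49a and Smo in 0.407%, 1.19% and 4.48% of cells, all fewer than in B6 DN1d cells. The level count fell from 26 to 8 with the median over cells and to 3 of 30 genes in cells with the gene detected, and in both 0 of these were lower.

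The fourth comparison asked which genes were detected in the same B6 DN1d cells as Sox13. Genes of the Tgd17 programme were. Blk was detected in 86.1%, 93.5% and 65.4% of the Sox13-detected cells of runs 1, 2 and 3 and in 0%, 0% and 3.64% of the others. Its mean natural log odds ratio over the 3 runs was 5.52 ± 0.55 (limma SE). This SE rests on the spread pooled over genes, so that it does not show how well the runs of a single gene agree. The mean was 4.45 for Cd163l1, 4.11 for Myb, 4.07 for Etv5, 3.53 for Gzma, 3.51 for Il17re, 3.03 for Ccr9, 2.84 for Maf, 2.63 for Tox, 2.61 for Vg2-Jg1 and 2.45 for Tcf7. Csf2rb2, which encodes a beta chain of cytokine receptors, was detected in 0 Sox13-detected cells of any run and in 22.2%, 23.1% and 30.9% of the others, a mean of -3.08. Cdh1, the E-cadherin gene, followed at -2.5, Bhlhe40 at -2.21, Gp49a at -2.16 and Spi1 at -2.08. Of 41 genes tested, 17 were detected with Sox13 more often than chance would give and 5 less often. Adjusted for the number of other genes detected in the cell, 11 were positive and 7 negative, 16 of these 18 among the 22, and Bcl11b, Lef1, Smo, Tcf12, Tcf7 and Tox no longer passed. Of the 9 Tgd17 programme genes tested, 7 were past the threshold, all positive, as they were adjusted over the list alone, and Sox4 (1.12, adjusted p = 0.0772) and Il7r were not. Of the 8 T lineage specification genes, 3 were positive (Tcf7, Bcl11b and Lef1) and 5 did not pass, with 3 adjusted over the list alone. Bcl11b had a mean of 1.88, positive in 2 of the 3 runs, and its call ended without run 1 or run 2. Tox was the positive innate lymphoid gene of 4, Myb was positive and Spi1 negative of the multipotent progenitor genes, and both junctions were positive, with the same counts adjusted over the list alone. Of 4 HMG box and Wnt pathway genes 3 were positive, and 4 adjusted over the list alone. With Sox13 shuffled among the cells of each run, a mean of 0.05 genes was called over 100 shuffles. The fit pooled the spread over the 41 genes, which share the same Sox13-detected cells, so that the adjusted p-values here may be too small.

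**Figure D2:**
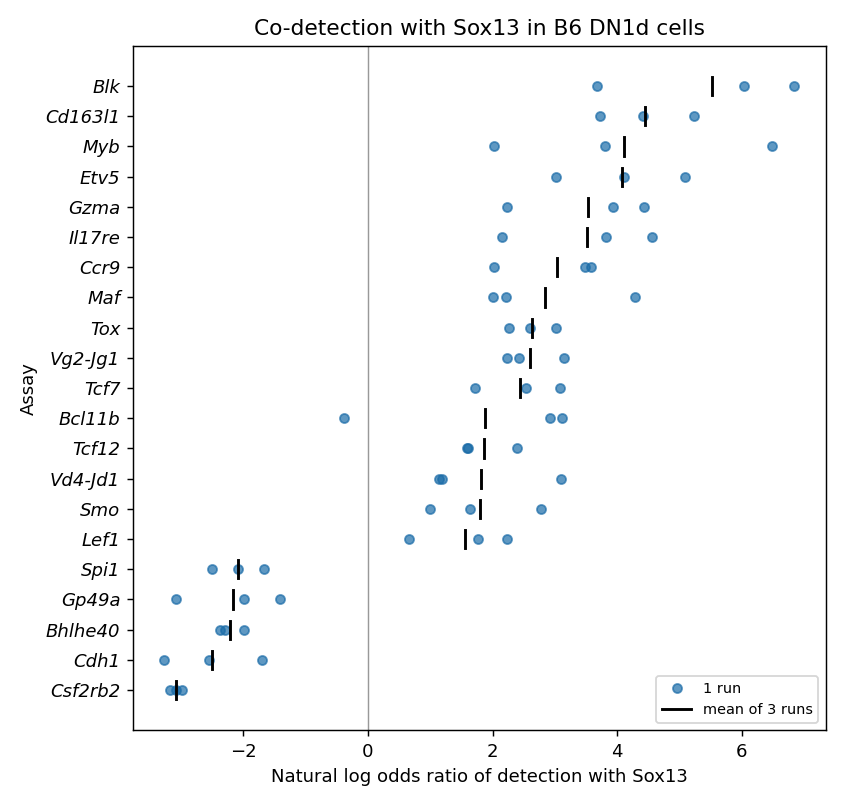
Natural log odds ratio of detection with Sox13 (horizontal axis) for 21 of the genes past the threshold in B6 DN1d cells (vertical axis), with 1 point per run and a black line at the mean of the 3 runs. Blk has the highest mean, 5.52, and Csf2rb2 the lowest, -3.08; Bcl11b is the gene whose runs fall on both sides of 0.

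The last comparison asked the same of Rag1-/- cells, in which Sox13 was detected in 10.3% ± 6.06 of cells. The mean natural log odds ratio over the 3 runs was 2.87 ± 0.55 (limma SE, pooled over genes) for Ccr9, 2.42 for Il17re, 2.41 for Blk and 1.64 for Maf. Gzma, at -1.62, Bhlhe40, at -1.63, Tbx21, at -1.78, and Syk, at -1.91, were detected with Sox13 less often, but the calls of Tbx21 and Syk ended when single runs were left out, and so did those of Maf, Runx1 and Zbtb16. Sox4 (0.38) and Bcl11b (1.10) did not pass. Of 41 genes, 16 were positive and 6 negative, but this count holds calls that the measure makes without any association. Cpa3, Rag2, Vg2-Jg1 and Vd4-Jd1 were detected in 0 Rag1-/- cells and were called at 2.22, which comes from the 0.5 added to each cell of the table. With Sox13 shuffled among the cells of each run a mean of 9.06 genes was still called, among them those 4, Csf2rb2 and Id2 in each of 100 shuffles, Spi1 in 84, Gp49a in 72 and Tbx21 in 16. Where gene and Sox13 each had at least 5 detected and 5 undetected cells in a run, which left out run 2 with its 2 Sox13-detected cells, 8 of 30 genes were positive and 2 negative. Without run 1 the count fell to 9. Of the 9 Tgd17 programme genes 4 were positive, Il17re, Blk and Maf among them, and 5 did not pass, and of 8 T lineage specification genes 3 were positive, Rag2 among them, and 5 did not pass. Of the 4 innate lymphoid genes Zbtb16 was positive and Id2 negative, of the 2 multipotent progenitor genes Spi1 was positive, of 4 HMG box and Wnt pathway genes Lef1 was positive, and both junctions were positive. Adjusted over the list alone, these counts were the same.

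The difference between Rag1-/- and B6 DN1d cells in co-detection with Sox13 passed the threshold for 15 of 41 genes, 5 of them higher and 10 lower in Rag1-/- cells. With Sox13 shuffled, a mean of 4.56 genes and at most 10 were called. With at least 5 cells on each side 9 of 30 genes passed, 8 of them among the 15, and with pseudocounts in proportion to the margins 6 passed, 5 of them among the 15. Gzma differed by -5.15 ± 0.78 (limma SE, pooled over genes), Myb by -4.28, Cd163l1 by -3.58 and Blk by -3.11. Maf differed by -1.20, Sox4 by -0.74 and Bcl11b by -0.78, none past the threshold. Of the 9 Tgd17 programme genes 3 were lower and 6 did not pass, of 8 T lineage specification genes 1 was higher (Runx1), 2 were lower (Notch1 and Tcf7) and 5 did not pass, and of 4 HMG box and Wnt pathway genes 2 were lower and 2 did not pass. Of the 4 innate lymphoid genes Zbtb16 was higher and Tox lower. The calls of Runx1, Notch1, Zbtb16 and Tox ended when single runs were left out, and Tcf7 could not be tested with at least 5 cells on each side, since too few Rag1-/- cells were without it. Of the 2 multipotent progenitor genes Myb was lower and Spi1 higher, a call that shuffled values also gave in 25 of 100 shuffles. The junctions were detected in 0 Rag1-/- cells, so that their difference says nothing of association. Adjusted over the list alone, these counts were the same.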

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

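The tests of composition and of rearranged cells in Tcrd-/- mice, of B6 DN1d run 3, of the splits of runs, the shuffles and the minimum of 5 cells on each side were chosen only after the results were seen, and the test of equal amplification replaced an earlier one as described below.

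Co-detection with Sox13 differed between Rag1-/- cKit- and B6 DN1d cells, by a test of the difference itself, for 15 genes. In log odds ratios, Rag1-/- minus B6, the difference was -5.15 for Gzma, -4.28 for Myb, -3.63 for Etv5, -3.58 for Cd163l1, -3.41 for Tcf7, -3.11 for Syk, -3.11 for Blk, -2.47 for Tox, -2.44 for Tbx21 and -1.88 for Notch1. It was 4.93 for Csf2rb2, 3.56 for Spi1, 3.46 for Gp49a, 2.55 for Zbtb16 and 1.92 for Runx1. Of the 15, 8 were also past the threshold where each side had at least 5 cells: Gzma, Myb, Cd163l1, Syk, Blk, Zbtb16, Tox and Runx1, but the calls of Zbtb16, Tox, Runx1, Notch1 and Tbx21 ended when single runs were left out, and for Myb only run 3 of the Rag1-/- runs had 5 cells with the gene. The differences of Csf2rb2, Gp49a and Spi1 carry little weight, since shuffled Sox13 values gave the same call in 39, 27 and 25 of 100 shuffles. Of the 10 splits of the 6 runs, 1, the real one, gave 15 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

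Of 47 genes, 26 were detected in more Tcrd-/- than B6 DN1d cells and 0 in fewer. Better amplification, as an equal gain of up to 2 cycles in every gene, is argued against, since with every Tcrd-/- level lowered by 2 cycles 26 genes were still detected in more cells and 1 in fewer. A larger share of the Sox13-detected cells that B6 mice also hold was tested as the whole cause. For 13 of 25 called genes the 95% interval lay above the share predicted from every B6 DN1d run. That interval covers counting error in the Tcrd-/- run and no error in the predictions. The interval of 5 (Cpa3, Runx1, Smo, Tcf3 E47 and Vd4-Jd1) also lay above the 95% prediction limit over the 3 runs. For Cpa3, Runx1, Smo and Tcf3 E47 this explanation is argued against as the whole cause. For Vd4-Jd1 the test cannot decide, since the gate against the delta chain may remove rearranged cells from B6 and so lower its prediction. For others, such as Bcl11b, Blk and Maf, the limit was 272%, 149% and 129%, so that no share could pass it. There the test could not decide. Adjusted for the number of other genes detected, 9 genes passed, 7 of them among the 26, but that number is made up in part of the genes in question, and more RNA per cell, better capture of transcripts and an unequal gain were not tested and stay open. Cells with rearranged receptor genes that the gate keeps only in Tcrd-/- mice may contribute, with Vd4-Jd1 in 52.3% of cells, but gate, genotype and run cannot be told apart in 1 run.

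The test of equal amplification was not the first. The first counted the genes higher in level after Gapdh normalisation, 29, by a rule written after that count was seen, and was set aside because normalisation cannot bring undetected reactions back. The rule for the test that lowered levels by 2 cycles was written before its value of 26 was computed, but after the 29 and the counts of 26 at detection limits of 22 and 20 were known.

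Bcl11b was detected in 37% of the cells of B6 DN1d run 3 against 90.3% and 85.7% in the other runs. Less RNA in run 3 is argued against by its Gapdh level of 14.65, which lies between 15.09 and 14.18 in the others. Fewer Sox13-detected cells are argued against, since Bcl11b was detected in 30.8% (14.3% to 51.8%) of the Sox13-detected cells of run 3 and in 100% of those of both other runs. An assay that worked differently in run 3 is a candidate explanation, since the E12 form of Tcf3 also stood apart, at 86.4% against 41.7% and 41.4%, while the E47 form did not. The E12 share also varied between the Rag1-/- runs, from 46.2% to 75.6%, so that its shift alone is weak evidence. The search for assays that stood apart in run 3 used shares of cells only. By level Tbx21 stood apart too, at 8.36 in run 3 against 4.25 and 2.67 in runs 1 and 2. Assay efficiency was not measured, another make-up of the cells of run 3 stays open, and no biological explanation was tested.

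Innate genes were higher in Rag1-/- cKit- cells, and B6 DN1d may hold a few cells of the same kind. In B6 DN1d the genes higher in Rag1-/- cells exceeded the other genes in median log odds ratio with Zbtb16 by a mean of 0.468. The difference was 0.893, 0.667 and -0.156 in runs 1, 2 and 3, with 6, 9 and 3 Zbtb16-detected cells, too few to decide. Genotype, age and gate stay open as untested. Of the 10 splits of the 6 runs, 1, the real one, gave 26 genes by level and 28 by detection, the highest other gave 0 in each, and 10 splits are too few for a share under 0.05.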

How the results depend on the processing

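A limit of detection of 20, pseudocounts in proportion to the margins, a minimum of 5 cells on each side and the count of cells left out by the filter on few detected genes were chosen only after the data were seen. Higher limits of detection (26, 28 and 30) were not run because no value lies above 24. No paired analysis was possible because no run holds cells of more than 1 group. The results rest on detection more than on level in detected cells, since 50.5% of reactions were undetected. For the named genes reported here 3024 values under alternatives kept direction and side of the threshold, 289 fell short of it, 26 came past it and 30 changed direction, 13 of these past the threshold in the main analysis. The cause of the changes was not tested.

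In cells with the gene detected only, of 30 genes, 3 passed by level in DN2 against DN1d, 2 in Tcrd-/- against B6 DN1d and 3 in Rag1-/- against B6 DN1d. With the median over cells the level counts were 14 in DN2 and 8 in Rag1-/- cells. With detection adjusted for the number of other genes 9 passed in Tcrd-/- cells, 7 of them among the 26 that passed without it. With the log odds ratio so adjusted, 11 genes were positive and 7 negative in B6 DN1d co-detection. With cells with few detected genes left out, 26 genes were detected in more and 5 in fewer Tcrd-/- cells, by a filter that left out 8 Tcrd-/- and 0 B6 DN1d cells. In Rag1-/- cells co-detection with Sox13 gave 12 genes by Spearman correlation, 10 with at least 5 cells on each side and 20 with margin pseudocounts (12 higher and 8 lower), 12 of the 20 among the 22 that passed without them. The difference from B6 gave 21 of 37 genes by Spearman correlation (3 higher and 18 lower), 9 with at least 5 cells on each side and 6 with margin pseudocounts. Leaving out 1 run at a time, DN2 gave 17 to 27 genes by level and 30 to 36 by detection, Tcrd-/- 24 to 31 and 23 to 26, and Rag1-/- 21 to 26 and 25 to 31. Co-detection gave 19 to 24 in B6 DN1d, 9 to 22 in Rag1-/- cells and 10 to 15 for the difference. Calls ended without 1 run for 9 of 25 named genes by level and 1 of 25 by detection in DN2, 7 of 25 and 5 of 24 in Tcrd-/-, 6 of 26 and 2 of 25 in Rag1-/-, and for co-detection 1 of 15 in B6 DN1d, 7 of 14 in Rag1-/- cells and 5 of 15 for the difference. By detection in Tcrd-/- cells these were Bcl11b, Ccr9, Cd163l1, Il17re and Syk.

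Direction changed as follows. With detection adjusted for the number of other genes, DN2: Sox13 -0.363, Bcl11b -0.115, Gata3 -0.0508. Rag1-/-: Maf -0.258. Tcrd-/-: Blk -0.260, Myb -0.485, Ccr9 -0.266, Tox -0.785, Tcf7 -1.19, Vg2-Jg1 -0.997, Cd163l1 -0.610, Il17re -0.740, Gata3 -0.107, Zbtb16 -0.850. In cells with the gene detected only, DN2 level: Tox -0.0169. Gapdh-normalised level of Gata3: DN2 -0.198, Rag1-/- -0.115. Log odds ratio adjusted for the number of other genes, Sox4: B6 DN1d -0.387, difference 0.668. Rag1-/- co-detection: Csf2rb2 -0.0480 by Spearman correlation, and with margin pseudocounts Csf2rb2 -1.31 and Id2 1.32. Difference with margin pseudocounts: Maf 1.25, Sox4 1.64, Bcl11b 1.20. Leaving out 1 run at a time, the differences ranged as follows. Bcl11b ran from -0.0837 (without B6 DN1d replicate 3) to 1.26 (without replicate 1) in DN2 detection and from -0.277 to 1.07 in Rag1-/- detection, by the same replicates. Zbtb16 in Tcrd-/- cells ran from -0.126 (without B6 DN1d replicate 3) to 0.495 (without replicate 2) in detection and from -0.178 (without replicate 3) to 0.0990 (without replicate 2) in level. Sox4 co-detection in Rag1-/- cells ran from -0.110 (without Rag1-/- replicate 1) to 0.726 (without replicate 2).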

Other observations

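The hypothesis tested here was formed from the co-detection results, and its test was fixed before its value was computed, while the shuffles and the sets of other genes were chosen only after it was seen.

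In B6 DN1d, Csf2rb2 and Spi1 were detected in 0 of 93 Sox13-detected cells, Cdh1 in 1 and Gp49a and Bhlhe40 in 3 each. Csf2rb2, Gp49a, Cdh1, Bhlhe40 and Spi1 may mark 1 kind of Sox13-undetected cell in B6 DN1d. Among the 36, 39 and 55 Sox13-undetected cells per run, the median log odds ratio of their 10 pairs was 2.5, 2.67 and 2.22. The mean was 2.46, and with 0.5 added to each cell of the table each of the 10 pairs was above 0 in each run. For Bhlhe40 and Spi1 in run 2 the sign of 0.179 rests on that 0.5. Of 39 cells, 10 held Bhlhe40, 4 held Spi1 and 1 held both. With each gene shuffled among the Sox13-undetected cells of each run, the mean was 0.0741 and the highest of 1000 shuffles was 0.618. Sets of 5 drawn from 19 other genes detected in 5% to 40% of these cells had a median of 0.600, and the highest of 1000 sets was 1.69. The 5 genes were picked for rare detection with Sox13 in these same runs. The 19, among them Ccr9, Etv5 and Myb, were not, so that neither the shuffles nor the sets account for that choice. The pairs of Csf2rb2, Gp49a and Cdh1 had the highest means, 4.54 ± 0.740 (SD, n = 3) for Gp49a and Cdh1, 4.26 ± 0.223 for Csf2rb2 and Gp49a and 4.24 ± 0.225 for Csf2rb2 and Cdh1. The 4 pairs with Bhlhe40 had the lowest, 0.723 ± 0.494 with Spi1, 1.02 ± 0.872 with Cdh1, 1.15 ± 1.08 with Csf2rb2 and 1.54 ± 1.09 with Gp49a. The random sets are medians over 10 pairs and no reference for single pairs. Whether Bhlhe40 stands apart from the other 4 genes was not tested. Few cells stand behind these values: Csf2rb2 and Gp49a were detected together in 7, 8 and 14 cells, and Bhlhe40 and Spi1 in 1, 1 and 6. The 0.5 added to each cell of a table pulls such values for rare genes away from their true size, and the identity of the cells was not tested. All 3 Sox13-undetected Tcrd-/- cells held Csf2rb2, Gp49a and Cdh1, with Bhlhe40 in 2 and Spi1 in 1. Sox13-undetected Rag1-/- cells held Cdh1 and Bhlhe40 in 39.9% and 61.6%, but Csf2rb2, Gp49a and Spi1 in 0.505%, 1.52% and 1.01%. There the 5 genes did not mark the same cells. Sox13-detected DN2 cells held Spi1 in 82.6% and Csf2rb2 in 0%.

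The overlap of the junction assays in the DN1d populations is given here as counts with no test. Each junction was detected in a larger share of Tcrd-/- cells, so that the counts alone do not show whether the overlap differs. Of 86 Tcrd-/- cells, 40 held Vd4-Jd1 and Vg2-Jg1, 5 only Vd4-Jd1, 27 only Vg2-Jg1 and 14 neither. Of 223 B6 DN1d cells, 9 held both, 7 only Vd4-Jd1, 83 only Vg2-Jg1 and 124 neither.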
